A study of Homo sapiens with 4 samples.

How the data were processed

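Total RNA of 4 HAP1 libraries was made into PCR-amplified cDNA with an Oxford Nanopore kit and sequenced on a MinION, per the labels' protocols. The deposited count table holds whole-number read counts per gene, not normalised, for 60662 genes, of which 26477 had a count. The submitters' processing notes name the hg38 build and the tools minimap2, SAMtools, Subread, DESeq and DESeq2 1.22.2. Their settings, the gene annotation and whether counting used strand are not given in the sources used here. A second deposited table holds a normalised signal, the counts divided by 1 size factor per library, which was 0.938 for WT A, 1.54 for WT B, 0.934 for KO clone 1 and 1.09 for KO clone 5; it was used to read these factors and to check the direction and the mean levels of the authors' table. The authors' deposited table of comparisons gives a mean normalised signal, a log2 fold change with its error, a Wald score and p-values for 6479 genes, per the file headers; that the mean is over 5 libraries was inferred from the values.

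The columns of the KO clones carry the clone numbers of the labels. The WT columns carry the product number of the WT line and no replicate number, so each was taken as a WT replicate without a number, called A and B. One WT column name also carries the tag FACS and the other the tag test. What these tags mean is not given in the sources used here, so the WT libraries may have been handled differently, by cell sorting for example, and their spread may include this. The number of count columns left unused was 0. Library totals ran from 3121759 to 5303199 counts, with a median of 44, 76, 48 and 54 counts per tested gene in WT A, WT B, KO clone 1 and KO clone 5, so the depth limits what can be said of genes near 10 counts.

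The groups, the tests, the lists, the rule for naming genes and the alternative settings were fixed before the data were examined. Both KO libraries were compared with both WT libraries in edgeR 4.0.16 (R 4.3.3): filterByExpr on the group (minimum count 10, minimum total 15), TMM scaling, a robust quasi-likelihood fit and a two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the 10505 genes tested and a threshold of 0.05. The common dispersion gave a biological coefficient of variation of 0.210. No pairing was fitted. The SE is the log2 fold change over the square root of the F statistic. CPM used the TMM-scaled library sizes. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and a ratio with 1 to 3 counts carries an exact Poisson interval.

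The 17 fixed lists held 484 entries: interferon-stimulated genes, nucleic acid sensing, NF-kB and inflammatory genes, MHC class I antigen presentation, MATR3 partners and nuclear RNA-binding proteins, p53 targets, proliferation, unfolded protein and ATF4 response, cholesterol biosynthesis, glycolysis and hypoxia, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, extracellular matrix and mesenchymal markers, epithelial, haematopoietic and neuronal markers, and germline and cancer-testis genes. Each list with at least 2 tested members was tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01, and adjusted over 16 lists. Genes were also adjusted over the list alone. These values were not corrected for the number of lists, so a gene called only there is a weaker call than one over all genes. The rule for named genes took MATR3, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 20 counts and both KO libraries beyond both WT libraries, up to 4 members with the lowest p of each list, and STING1, CGAS, IFNB1, ISG15, IFI6 and CXCL10. Any other gene named was chosen after its values were seen.

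Gene positions came from GENCODE 44 on hg38. Of the 60662 genes 41297 were placed, 35726 by symbol, 1130 by an older symbol and 4441 by gene identifier. The best split of each chromosome was found by least squares over the fitted log2 fold changes, with at least 20 genes on each side. The longest protein-coding transcript of 19702 genes was aligned to the 261 alternate contigs of hg38 with minimap2 2.31, and an alternate copy was counted where at least 80% of the transcript aligned at an approximate identity of at least 98%. A first measure of identity, which counted introns as mismatches, was replaced because it left too few genes to compare.

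The alternatives were RLE and upper-quartile scaling, no scaling, mitochondrial genes left out, no count filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, an added log2 fold change of at least 1, each library left out in turn, and for lists camera with an estimated correlation and the fry rotation test. With an estimated correlation, several lists shared an adjusted camera p of 0.665 as a result of the adjustment, so this value does not rank them. That setting takes its degrees of freedom from the 4 libraries and not from the genes, so few lists could pass. The 185 genes of a chromosome 6 segment, chosen from these data, had an unadjusted camera p of 3.19e-38 at the preset. With their estimated correlation of 0.0096 it was 0.00573. A higher p in that setting is therefore no sign against a list. Where a library was left out, the lone library of its group was assumed to vary like the other group. The steps were tested on simulated counts drawn for the real genes with the real library sizes and spread, with 200 genes changed. Of the 2-fold changes that reached the test edgeR called 21 of 93 and of the 4-fold changes 88 of 96, over 10052 genes, and 4.39% of its calls were unchanged genes. With no list changed, camera called 0 of 16 lists. Counts were drawn separately for each gene, so this could not show false calls from correlated members of a list. The spread was the one edgeR fitted to these data, and no difference of date, clone or handling was simulated. The share of unchanged genes among the simulated calls is therefore no measure of the error rate of the real calls. The figures were drawn with matplotlib 3.10.9.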

Results

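MATR3 encodes matrin 3, a nuclear matrix protein that binds RNA and DNA. The comparison asked how gene expression differs between cells with and without it, and the title of the series names activation of the cGAS and STING pathway, which senses DNA in the cytosol and induces interferon-stimulated genes. The cells were HAP1, a near-haploid human line derived from the chronic myeloid leukaemia line KBM-7. Total RNA was read as PCR-amplified cDNA on an Oxford Nanopore MinION, a long-read sequencer. There were 4 libraries, 2 from wild-type (WT) clone 4 and 1 each from the purchased MATR3 knockout (KO) clones 1 and 5. The WT libraries, called A and B here, held 3509906 and 5303199 counts, KO clone 1 held 3121759 and KO clone 5 held 4024026. The labels name no separate cultures for the WT libraries, so p-values measure only the spread between these libraries, which may be technical. The KO libraries carry another date tag than the WT libraries, so date and genotype cannot be told apart.

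MATR3 transcripts were present in all 4 libraries, and no difference between the groups was called. MATR3 is annotated as 2 overlapping gene models on chromosome 5 (hg38). The main model, ENSG00000015479, spans 139293674 to 139331677 and had 171 and 304 counts in WT A and B, 187 in KO clone 1 and 204 in KO clone 5. Its level was 53.8 ± 4.11 CPM (counts scaled to library size) in WT (SD, n = 2) and 55.1 ± 3.27 in KO (SD, n = 2), a log2 fold change of 0.03 (SE 0.28, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.974). The longer model, listed as MATR3, starts at 139273752 and had 41, 43, 27 and 37 counts in the same order, with a log2 fold change of -0.15 (SE 0.35, edgeR adjusted p = 0.875). The models share 42.6% and 80.9% of their exonic bases, so reads of one can be counted under the other. A count summed over a gene does not detect a small edit, and where the clones were edited is not given in the sources used here, so these counts do not check the KO labels.

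Of the 10 genes with the largest falls in the KO clones among those with a mean of at least 20 counts, 3 had 0 counts in both clones. S100A6, a calcium-binding protein of the S100 family, fell from 749 ± 23.7 CPM in WT to 4.35 ± 0.0713 CPM in KO (SD, n = 2 each), with 2461 and 4106 counts against 14 and 17 and a log2 fold change of -7.42 (SE 0.32, edgeR adjusted p = 1.75e-08). MGMT, the methyltransferase that repairs O6-alkylguanine in DNA, had 130 and 162 counts in WT and 0 in both KO clones, at least 79.5-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 2.35e-05). FASTKD2, a mitochondrial RNA-binding protein, and MYOM1, a sarcomere protein, also had 0 counts in both clones, at least 29.4-fold and at least 25.9-fold lower (edgeR adjusted p = 0.000335 and 0.000643). Floors and counting intervals cover counting error only, since PCR copies are not independent molecules. AMBN, an enamel matrix protein, had a log2 fold change of -6.27 (SE 0.59), the unplaced gene AC091493.1 of -4.34 (SE 0.50), the esterase gene IAH1 of -3.62 (SE 0.44), the actin-like gene ACTL8 of -3.41 (SE 0.64) and the ketosteroid reductase gene AKR1C3 of -3.38 (SE 0.57). PPP2R2B, a regulatory subunit of protein phosphatase 2A, had 113 counts over the WT libraries and 1 over the KO libraries, a ratio of 92.2 with a 95% exact counting interval of 16.2 to 3675. AKR1C3 has close paralogs, between which reads could be split.

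Apart from TCEAL9, the genes with the 10 largest rises among those with a mean of at least 20 counts began from low WT levels. NEFL, the light chain of neurofilaments, rose from 0.726 ± 0.236 CPM in WT to 47.1 ± 22.4 CPM in KO (SD, n = 2 each), with 3 and 3 counts against 205 and 121 and a log2 fold change of 6.02 (SE 0.53, edgeR adjusted p = 4.38e-05). TPM2, the beta chain of tropomyosin, rose from 9.11 ± 1.10 to 202 ± 53.1 CPM, a log2 fold change of 4.46 (SE 0.34, edgeR adjusted p = 1.56e-05). TCEAL9 was the most abundant of the 10 genes with the largest rises, at 76.6 ± 30.1 CPM in WT and 558 ± 62.9 CPM in KO, a log2 fold change of 2.87 (SE 0.30). It lies 101 kb from TCEAL8, which had 0 counts in both KO clones. The other genes of this group were POF1B, an actin-binding protein, with a log2 fold change of 4.19 (SE 0.46), SPARCL1, a matricellular protein, with 3.28 (SE 0.43), and LY96, the MD-2 co-receptor of TLR4, with 3.13 (SE 0.49). The transcription factor TBX3 had 3.01 (SE 0.40), the endopeptidase MME 2.87 (SE 0.34) and the Wnt receptor FZD10 2.86 (SE 0.59). The stratifin gene SFN rose 8.02-fold, from 0 and 13 counts to 47 and 35 (edgeR adjusted p = 0.0301).

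**Figure D1:**
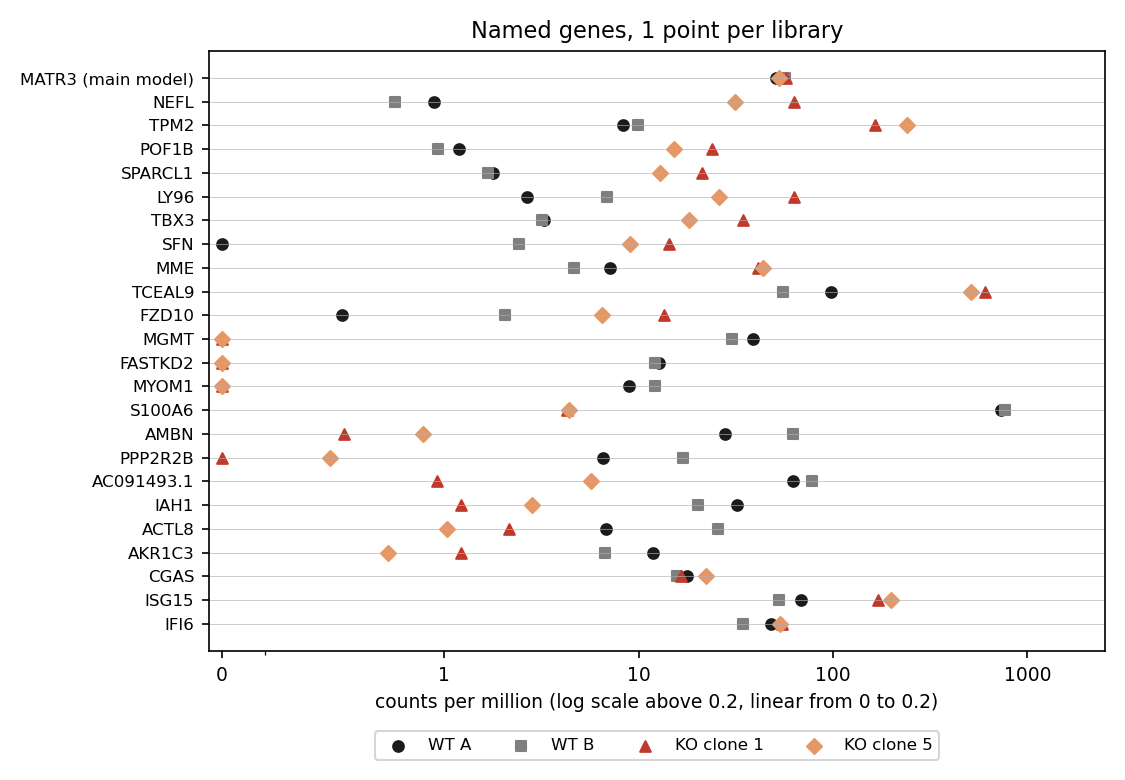
CPM of each library for the main MATR3 model, the 10 genes with the largest rises, the 10 with the largest falls, and CGAS, ISG15 and IFI6, on an axis that is logarithmic above 0.2 and linear below it; each point is 1 library. The 20 genes with the largest changes were chosen to have a mean of at least 20 counts and both KO clones on one side of both WT libraries. The MATR3 points of all 4 libraries overlap.

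Across all 10505 genes tested, 166 rose and 64 fell in the KO clones at an edgeR adjusted p under 0.05, and 1718 had an unadjusted p under 0.05. Of these, 164 rose and 64 fell by at least 2-fold, and 54 rose and 43 fell by at least 4-fold. In all 230 changed genes both KO libraries lay beyond both WT libraries, which the choice of genes by p with 2 libraries a side already favours. On simulated counts with the spread of this comparison, edgeR recovered 91.7% of 4-fold changes and 22.6% of 2-fold changes, so many smaller changes were not detectable with 2 libraries a side. Without any scaling factor 20 genes rose and 11 fell, without KO clone 5 the counts were 674 and 361, and without WT library A they were 91 and 156. Without any scaling factor the calls of LY96, SFN, FZD10, ACTL8, AKR1C3, PARP9, BUB1, MT-ND6, KRT8 and DPYSL3 ended, and with limma-voom those of FZD10, ACTL8 and PARP9. Lower calls numbered 24 with DESeq2, which called 160 higher, and 41 with limma-voom. DESeq2 gave an adjusted p for 6383 genes and limma-voom for 10505, so these counts rest on different sets of genes.

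**Figure D2:**
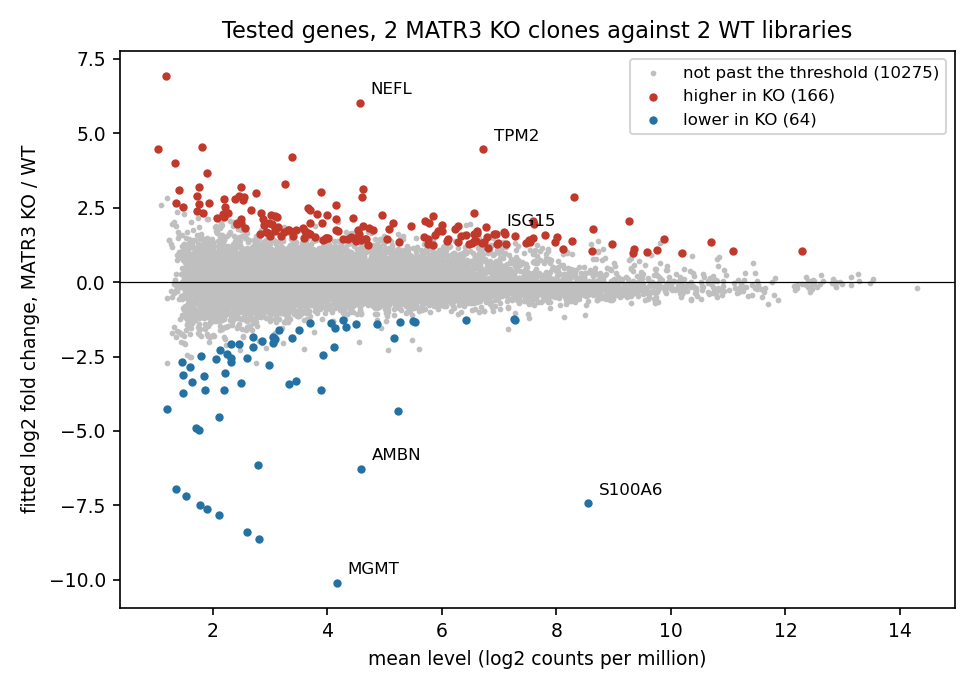
Fitted log2 fold change (MATR3 KO over WT) against mean level in log2 CPM for the 10505 genes tested, 1 point per gene; red points are the 166 genes that rose, blue points the 64 that fell and grey points the genes not past the threshold. The fitted value of a gene with 0 counts in 1 group, such as MGMT, is not a measured fold; S100A6 stands apart as an abundant gene with a log2 fold change of -7.42.

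The 2 KO clones also differed from each other. The chi-square per degree of freedom of their counts over the tested genes was 15.2, against 6.49 between the WT libraries and 12.5 between KO clone 5 and either WT library, while KO clone 1 stood at 28.0 and 24.6 from WT A and B. Each pair differed by more than counting noise, which PCR-amplified repeats of 1 sample would do as well, so this does not show whether the WT libraries are repeats. The Spearman correlation across genes was 0.948 between the KO clones and 0.960 between the WT libraries. It was 0.936 and 0.942 between KO clone 5 and WT A and B, and 0.897 and 0.920 for KO clone 1. By this measure KO clone 5 was nearer to KO clone 1 than to either WT library, the reverse of the chi-square order. The chi-square was taken on raw counts, so it grows with depth and is weighted to abundant genes, while ranks are not. The order of the pairs by chi-square alone therefore does not rank how alike the libraries are. AC091493.1 had 3 counts in KO clone 1 and 22 in KO clone 5, and LY96 had 205 and 100. Each clone has 1 library, so a difference between the clones has no replicate check. The calls of ACTL8 (highest adjusted p 0.476), PARP9 (0.180), SFN (0.251) and FZD10 (0.119 without KO clone 1) ended when certain single libraries were left out, with edgeR adjusted values. The fitted log2 fold change of SFN was 2.26 without WT library A, and without WT library B it has no measured value, since WT A had 0 counts. That of FZD10 was 2.26 without WT library A, 4.87 without WT library B and 2.28 without KO clone 1, and that of LY96 was 2.35 without KO clone 1 and 4.00 without WT library B. That of AC091493.1 was -3.62 without KO clone 1 and -6.21 without KO clone 5, and that of ACTL8 was -2.13 without WT library B and -4.02 without WT library A. For AMBN it was -5.58 without WT library B and -7.08 without KO clone 5, for IAH1 -4.37 without KO clone 5 and for AKR1C3 -4.06 without KO clone 1. For PPP2R2B it was -5.25 without WT library B and -5.39 without KO clone 1, with no measured value without KO clone 5, since KO clone 1 had 0 counts.

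Among interferon-stimulated genes, ISG15, a ubiquitin-like modifier induced by interferon, rose in both KO clones. It had 230 and 283 counts in WT and 553 and 772 in KO, or 60.6 ± 11.1 against 185 ± 21.2 CPM (SD, n = 2 each), a log2 fold change of 1.61 (SE 0.28, edgeR adjusted p = 0.0116). PARP9, an ADP-ribosyltransferase family member, rose with a log2 fold change of 2.32 (SE 0.52, edgeR adjusted p = 0.0345) from 4 and 5 counts to 16 and 22. Of the 51 genes in this list 19 were tested, 2 rose, 0 fell and 17 did not pass. Adjusted over the list alone, with no correction across lists, 3 rose and 1 fell. The added calls were DTX3L, the partner of PARP9, 2.34-fold higher (SE 0.34 on the log2 scale), and IFIT1, an RNA-binding antiviral protein, which went the other way with -1.39 (SE 0.40). PARP9 and DTX3L overlap at their 5′ ends on chromosome 3. IFI6 had a log2 fold change of 0.40 (SE 0.29, edgeR adjusted p = 0.529). The list of interferon-stimulated genes as a whole did not pass (camera adjusted p = 0.164), but it passed among genes with a mean of at least 50 counts (0.0453); with an estimated correlation it had 0.665. Without WT library B the ISG15 log2 fold change was 1.41 with an edgeR adjusted p of 0.131, and PARP9 had an adjusted p of 0.180 there, 0.135 without KO clone 1 and 0.130 without KO clone 5.

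The sensors upstream of these genes showed no call. CGAS, the DNA sensor that makes cGAMP, had 60 and 85 counts in WT and 54 and 86 in KO, a log2 fold change of 0.21 (SE 0.31, edgeR adjusted p = 0.774). STING1, the adaptor that binds cGAMP, had 6 and 4 counts in WT and 2 and 2 in KO, too few to test. IFNB1, which encodes interferon beta, had 0 counts in all 4 libraries, and CXCL10, an interferon-induced chemokine, had 1 count in KO clone 1 and 0 in the other libraries. In the nucleic acid sensing list 0 of 16 tested genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.947). SAMHD1, a dNTP hydrolase, had the lowest p there, with a log2 fold change of 0.89 (SE 0.33, edgeR adjusted p = 0.187). In the list of NF-kB and inflammatory genes 5 were tested and 0 rose or fell, also adjusted over the list alone (camera adjusted p = 0.164); NFKB2 had a log2 fold change of 1.12 (SE 0.40) and SOD2 of 1.11 (SE 0.43). Of the 18 MHC class I genes 4 were tested and 0 rose or fell, also adjusted over the list alone (camera adjusted p = 0.950), with PDIA3 at 0.27 (SE 0.29) and CALR at -0.28 (SE 0.30). The median of those 4 genes was 0.04 and the test pointed down. In that list 9 genes, TAP1 among them, were listed at 0 counts and B2M at 3 over the 4 libraries. Of its 18 genes 11 have a near-identical copy on an alternate contig of hg38, and of these 10 were listed at 4 counts or fewer, so the list was hardly measured.

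The list of MATR3 partners and nuclear RNA-binding proteins held 1 gene that rose among 26 tested. HNRNPK, an RNA-binding protein of the heterogeneous nuclear ribonucleoproteins, went from 794 ± 3.98 to 1555 ± 10.2 CPM (SD, n = 2 each), a log2 fold change of 0.97 (SE 0.21, edgeR adjusted p = 0.0283). Adjusted over the list alone 2 rose, with TARDBP, which encodes TDP-43, at 1.42 (SE 0.36, edgeR adjusted p = 0.0618 over all genes), and 0 fell in either case. HNRNPL had 0.81 (SE 0.29) and SAFB2 -0.67 (SE 0.28), and 25 members did not pass (camera adjusted p = 0.516). HNRNPK has processed pseudogenes that could take or give reads, and its edgeR adjusted p was 0.343 without WT library A and 0.325 without WT library B.

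Neuronal and epithelial markers were the 2 lists of 16 tested that passed as groups. Only 5 of 18 neuronal and 4 of 20 epithelial markers had enough counts to be tested. The passes therefore speak for these few members and not for a neuronal or epithelial programme. Of 5 neuronal markers tested 2 rose, NEFL and DPYSL3, a protein of growth cones with a log2 fold change of 1.75 (SE 0.35, edgeR adjusted p = 0.0207), with the same 2 adjusted over the list alone and 0 lower. SOX2 had 0.30 (SE 0.23) and CRMP1 0.41 (SE 0.33), and the median of the list was 0.41 against a mean of 1.70 (camera adjusted p = 7.07e-05, and 0.665 with an estimated correlation). Of 4 epithelial markers tested 1 rose, KRT8, a simple-epithelium keratin, with a log2 fold change of 1.97 (SE 0.36, edgeR adjusted p = 0.0143, and 0.0651 without scaling). Adjusted over the list alone 3 rose, KRT8, its partner keratin KRT18 at 1.01 (SE 0.40) and SPINT1 at 0.93 (SE 0.39), and 0 fell (camera adjusted p = 0.0199, and 0.665 with an estimated correlation). Before adjustment, camera with an estimated correlation gave p = 0.0427 for neuronal and 0.0917 for epithelial markers. The estimated correlations were -0.22 and -0.24, below the preset of 0.01, so the higher p there does not show correlated members. It goes with the fewer degrees of freedom of that setting. With fry the adjusted p was 0.0608 for neuronal and 0.146 for epithelial markers, and the epithelial list had 0.0662 without WT library A and 0.139 without KO clone 5. KRT8 has many processed pseudogenes, and DPYSL3 had an edgeR adjusted p of 0.0644 without WT library A.

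Of the matrix list 1 gene passed over all genes, and of the haematopoietic and germline lists 0. In the extracellular matrix and mesenchymal list TPM2 alone rose among 14 tested and 0 fell; adjusted over the list alone COL5A2, a fibrillar collagen, was added at 1.49 (SE 0.42), making 2. SPARC had -1.15 (SE 0.46; -0.24 without WT library B) and VIM 0.41 (SE 0.30), and the median of the list, -0.13, had another sign than its mean, 0.29, and its test, which pointed up (camera adjusted p = 0.243). Among genes with a mean of at least 50 counts the list of extracellular matrix and mesenchymal markers passed (0.0453), and with an estimated correlation it had 0.665. Of 7 haematopoietic markers tested 0 rose or fell over all genes; adjusted over the list alone 3 rose, the transcription factors MYB at 1.89 (SE 0.54; 1.17 without KO clone 1), RUNX1 at 1.44 (SE 0.44) and GATA2 at 0.84 (SE 0.30) (camera adjusted p = 0.287). Of the germline and cancer-testis genes 1 was tested, DPPA4, with a log2 fold change of 0.11 (SE 0.23), and neither adjustment called it, so no list test was run.

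Growth, stress and metabolic lists held few calls. Of 28 proliferation genes BUB1, a spindle checkpoint kinase, rose with a log2 fold change of 1.26 (SE 0.28, edgeR adjusted p = 0.0301), the same 1 gene adjusted over the list alone, and 0 fell. CCNA2, cyclin A2, had -0.90 (SE 0.29) and CENPF -0.68 (SE 0.26), and 22 of the 28 lay below 0 (camera adjusted p = 0.126, and 0.0260 without WT library B, where the proliferation list passed as lower, and 0.665 with an estimated correlation). Without WT library A the adjusted p of BUB1 was 0.114 and without WT library B 0.337. Of 15 p53 targets 0 rose or fell over all genes; adjusted over the list alone 2 rose, CDKN1A, the cell cycle inhibitor p21, at 1.84 (SE 0.49; 0.91 without KO clone 1) and SESN1 at 1.07 (SE 0.33) (camera adjusted p = 0.158). Of 19 genes of the unfolded protein and ATF4 response 0 rose or fell by either adjustment (camera adjusted p = 0.950), with ATF4 at -0.51 (SE 0.27) and EDEM1 at 0.75 (SE 0.35). Of 17 cholesterol biosynthesis genes 0 rose or fell over all genes; adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.714). INSIG1 had 1.03 (SE 0.34), STARD4 1.01 (SE 0.35) and DHCR7 -0.99 (SE 0.30). Of 22 glycolysis and hypoxia genes 0 rose or fell by either adjustment (camera adjusted p = 0.126), with EGLN3 at -1.33 (SE 0.38) and HK1 at 0.89 (SE 0.32). The glycolysis and hypoxia list passed as lower without KO clone 5. With an estimated correlation, where few lists could pass, it had a camera adjusted p of 0.665.

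Few transcripts of the mitochondrial genome and of ribosomal proteins passed singly, and whether their lists passed depended on the setting. Of the 13 mitochondrially encoded mRNAs MT-ND6, the subunit encoded on the light strand, rose with a log2 fold change of 1.31 (SE 0.29, edgeR adjusted p = 0.0322), and 0 fell. Adjusted over the list alone 3 rose, with MT-ATP8 at 1.27 (SE 0.42; 0.32 without KO clone 1) and MT-CYB at 0.63 (SE 0.22), and MT-CO2 fell by 0.72 on the log2 scale (SE 0.24) (camera adjusted p = 0.108). The list of mitochondrially encoded mRNAs passed as higher without a count filter (camera adjusted p = 0.0153) and with WT library B or KO clone 5 left out. With an estimated correlation, where few lists could pass, it had 0.665. Whether counting used strand is not given in the sources used here, so MT-ND6 reads cannot be told from those of the opposite strand, and its edgeR adjusted p was 0.295 without WT library A and 0.119 without WT library B. The mitochondrial share of counts was 1.95% and 2.17% in WT A and B, 2.68% in KO clone 1 and 2.13% in KO clone 5. Of 74 ribosomal protein genes RPS12 rose, with a log2 fold change of 1.05 (SE 0.21, edgeR adjusted p = 0.0199), the same 1 gene adjusted over the list alone, and 0 fell. RPL22 had 1.06 (SE 0.31) and RPL8 -0.61 (SE 0.28), and 54 of the 74 lay below 0 (camera adjusted p = 0.126). The list of cytosolic ribosomal proteins passed as lower without WT library B (0.0323) and without KO clone 5 (0.00052), and turned direction without KO clone 1 (0.679). With an estimated correlation, which was 0.42 for this list, it had 0.843. RPS12 lies in the part of chromosome 6 described next, and its edgeR adjusted p was 0.0855 without WT library A and 0.335 without WT library B.

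Most tested genes of the distal long arm of chromosome 6 were higher in both KO clones. From GRIK2, at 100962701 (hg38, GENCODE 44), to 170584692, 185 tested genes had a median log2 fold change of 0.91, a fold of 1.88, and 93.5% of them lay above 0. The median was 0.84 in KO clone 1 and 0.97 in KO clone 5 relative to the WT mean, and the WT libraries differed by -0.05. The 288 tested genes of chromosome 6 before that point had a median of -0.01. Of the 158 genes that rose and could be placed, 37 lay in this segment, and 0 of the genes that fell lay there. TSPYL4, with a log2 fold change of 2.32 (SE 0.28, edgeR adjusted p = 0.00084), and OSTM1, with 2.22 (SE 0.32, edgeR adjusted p = 0.00366), were named after their values were seen. SESN1, SOD2, MYB and RPS12 of the lists lie in the segment, whose boundary was chosen from these data.

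**Figure D3:**
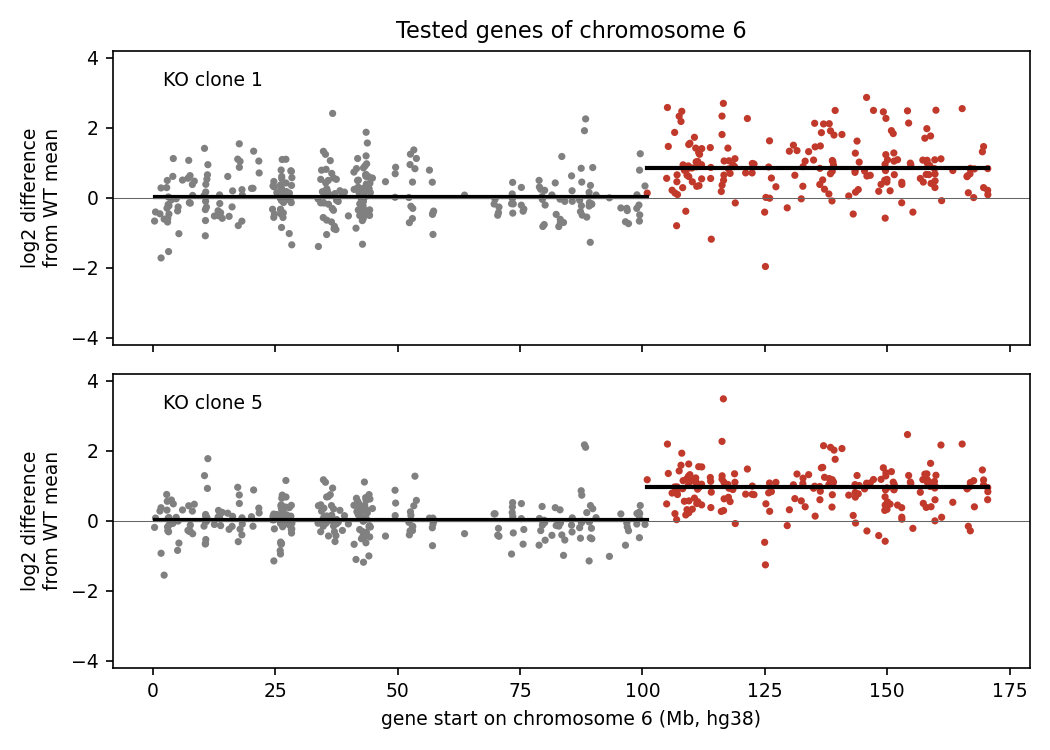
Log2 difference of each KO clone from the WT mean (log2 of CPM plus 0.5) against gene start on chromosome 6 in Mb (hg38), 1 point per tested gene; red points are the 185 genes from GRIK2 on and black lines the medians. The median steps from 0.03 to 0.84 in KO clone 1 and from 0.03 to 0.97 in KO clone 5.

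The authors' deposited table lists 6479 genes, of which 111 were higher and 18 lower at an adjusted p under 0.05. Of these 87 were also higher and 16 also lower here, 24 and 2 were called in the authors' deposited table alone, and 96 of the 230 genes called here are not listed there. The lowest mean level listed there was 33.3, and genes not listed could not be called there. Among the listed genes 112 were called higher and 22 lower here. ISG15 had a log2 fold change of 1.60 in the authors' deposited table with an adjusted p of 3.68e-05. The Wald statistic of the authors' deposited table has the opposite sign to the log2 fold change for 6478 genes and the same sign for 1, ISG15, so directions were read from the fold changes, whose sign matched the normalised counts for all 4357 genes with a difference over 0.2. The mean levels in that table are means over 5 libraries, since 5 times each mean less the 4 normalised columns was a whole multiple of 1 constant for all 6479 genes. The fifth library was not analysed here. The p-values there therefore rest on a fit that differs from the one here, and the overlap of calls is no independent check.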

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

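The alternatives that left out the distal chromosome 6 genes, summed both MATR3 gene models or changed the setting for the segment median were chosen after the data were seen; the others were fixed before. No paired analysis was possible because the WT libraries come from 1 clone and the KO libraries from 2 other clones, so nothing in the labels pairs them. The deposited table of comparisons rests on 5 libraries, so its p-values and those here come from different fits. Where a library was left out, its lone partner was assumed to vary like the other group. The causes of the changes listed here were not tested. Of 28 named genes past the threshold 0 turned direction, 10 lost the call in a setting that kept all libraries and 10 without some library; of the others 8 turned direction and 26 passed in some setting. That 0 of the called genes turned was largely set by their choice, since both KO libraries of each lay beyond both WT libraries in CPM. The segment median stayed between 0.84 and 0.98. The epithelial list had too few members for a test at a mean of at least 50 counts.

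Without scaling 20 genes rose and 11 fell; without a count filter 385 and 183; at a mean of at least 50 counts 71 and 12. DESeq2 called 24 genes lower of 6383 with an adjusted p and limma-voom 41 of 10505. Leaving out 1 library gave 91 (WT A) to 674 (KO 5) higher and 42 (WT B) to 361 (KO 5) lower. Lists higher numbered 0 with an estimated correlation, 0 with fry, and 1 to 3 without a library; lists lower 0 to 2.

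The model listed as MATR3 had a log2 fold change of -0.15, but 0.0028 with both models summed, and -0.469 (no WT B) to 0.1632 (no WT A) without a library. The main model had -0.0079 with upper-quartile scaling and -0.0371 (no WT A) to 0.0896 (no WT B) without a library. CANX had 0.0104 without scaling and 0.0134 at a mean of at least 50 counts. Without a KO clone the ranges of log2 fold changes were -0.0217 to 0.4078 for CGAS, -0.1295 to 0.791 for IRF3, -0.6554 to 0.0192 for CCL2, -0.6553 to 0.0138 for CALR, -0.2719 to 0.3577 for NLRC5 and -0.0651 to 0.0295 for CANX, and for CLDN3 without a WT library -0.1927 to 0.646.

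Some lists not past the threshold turned direction, given here with adjusted p. Nucleic acid sensing had 0.912 without a count filter and 0.85 at a mean of at least 50 counts, and MHC class I antigen presentation 0.492 without a filter and 0.938 with fry. The list of the unfolded protein and ATF4 response had 0.547 at a mean of at least 50 counts. Over the left-out libraries the values ran from 0.634 to 0.888 for nucleic acid sensing, 0.826 to 0.991 for MHC class I, 0.301 to 0.939 for unfolded protein and ATF4 (turned without KO 5), 0.576 to 0.972 for cholesterol biosynthesis (turned without KO 5) and 0.00052 to 0.748 for cytosolic ribosomal proteins (turned without KO 1, 0.679).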

Other observations

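The tests of the chromosome 6 segment and of ABCB1 with its neighbour were chosen after the results were seen, and so were the genes named here. HOTAIR, a long noncoding RNA of the HOXC cluster, had 0 counts in both WT libraries and 11 and 16 in the KO clones, at least 11-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0108). HOXC11, which overlaps it on the opposite strand on chromosome 12, rose from 1 and 10 counts to 25 and 41, a log2 fold change of 2.88 (SE 0.55, edgeR adjusted p = 0.0171), and without strand the reads of the 2 genes cannot be told apart. The neighbouring HOXC10 had a log2 fold change of -0.19 (edgeR adjusted p = 0.889) and HOXC9 of -1.21 (0.212). APOBEC3C, a cytidine deaminase, fell by 2.46 on the log2 scale (SE 0.44, edgeR adjusted p = 0.0131), and its neighbour APOBEC3F had 0.06 (0.954). OSMR, the oncostatin M receptor, had 20 and 24 counts in WT and 1 and 0 in KO, and the cyclin gene CCND2 35 and 44 against 7 and 4 (edgeR adjusted p = 0.0109 and 0.0165).

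The median over the 185 tested genes of distal chromosome 6 was higher by about the same amount in both KO clones. A candidate explanation is an extra copy of the segment in a near-haploid line, which would double expression; the lower of the clones' medians was 0.84 on the log2 scale. General differences between libraries are argued against, since the best split of any other chromosome separated medians by at most 0.38, against 0.92 on chromosome 6. A loss of 1 of 2 copies in WT cells that had become diploid would give the same ratio and stays open, as no DNA was analysed here. Both clones share the segment, so effects of MATR3 loss and of a shared lineage of the clones cannot be separated by the design; without these genes 122 genes rose and 59 fell.

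Among protein-coding genes of chromosome 6 that start between 29 and 33 Mb, the MHC region, 141 of 148 were listed at 0 in all 4 libraries, against 72 of 191 in the 5 Mb on each side. Reads lost to the alternate haplotype contigs of hg38 may account for part of this, but not by this measure for the 7 genes of the region without an alternate copy, of which 7 were also at 0. Outside chromosome 6, genes of families that every cell uses were listed at 4 counts or fewer for 12 of 16 with an alternate copy and 31 of 609 without, a ratio of shares of 14.7 (Fisher's exact test, two-sided p = 3.46e-12). IFI27, LY6E, IRF7 and CCL5 of the interferon list have such a copy and 4 counts or fewer, so their low counts need not mean that they were silent. No biological explanation was tested.

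A set of 8 genes past the threshold had counts in WT and 0 in both KO clones: MGMT, FASTKD2, MYOM1, TCEAL8, SH2D4A, ABCB1, SAMD12 and GALNT13. Deletions that reach the nearest tested neighbours are argued against for 7 of them, whose 14 such neighbours had a median log2 fold change of 0.0105 and a lowest of -0.61. The highest was 2.87, for TCEAL9, which lies 101 kb from TCEAL8 (edgeR adjusted p = 0.000306). Why TCEAL9 rose beside a gene with 0 counts in both KO clones was not tested. These neighbours lay 28 to 1870 kb away, so deletions that reach only nearer, untested genes stay open. For ABCB1 this cannot be told apart from lowered transcription of both genes, since its neighbour CROT, 103 kb away, had -4.52 (edgeR adjusted p = 0.00899). Deletions within a gene, silencing in the founder of the clones and an effect of MATR3 loss stay open and may differ between the genes.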
